A study of Mus musculus with 10 samples.

How the data were processed

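RNA was measured by bulk RNA sequencing in 10 libraries of freshly sorted mouse cells. Per the labels' protocols, skin or bone marrow was digested with enzymes, and cells free of CD45 (leukocytes), TER119 (erythroid cells) and CD31 (endothelial cells) were sorted as skin Ebf2+ cells (3 libraries), skin Ebf2- cells positive for CD140a and Sca1, called PαS (3 libraries), or bone marrow mesenchymal stem cells positive for Sca1 and CD51 (4 libraries). Per the labels' protocols, RNA was purified on micro-scale columns, cDNA was amplified with the SMART-Seq v4 kit, libraries were made with Nextera XT, and 75 bp single-end reads were generated on either of a pair of Illumina instruments. Which library ran on which instrument is not given in the sources used here.

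Per the submitters' processing notes, FastQC 0.11.8, MultiQC 1.7, STAR 2.6.1d, featureCounts of the Subread package and DESeq2 were used. Per the file headers, reads were aligned with STAR to the GRCm38 primary assembly and counted per Entrez gene with featureCounts. The header's name for the gene reference pairs the mouse with the name of a human build, and it is taken here only as written. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited raw counts are whole numbers for 14995 genes, 1 column per library, with no replicates pooled. The lowest total of any gene was 21 counts and each gene had a count in at least 3 libraries, so the deposited table had been filtered, by a rule not given in the sources used here. No mitochondrially encoded gene was listed. Spreadsheet dates had replaced 18 gene symbols, and all 18 were restored by their Entrez number. A further 251 genes carried no symbol and were named by number. The authors' deposited table also gives log2 fold changes and adjusted p-values from DESeq2, per the file headers. These log2 fold changes and p-values of the authors were used only for counts set beside the present ones. The 10 columns of the authors' normalized counts were not used.

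Columns were assigned to samples by name, taking the number after S in a column name as the replicate number in the sample's title. The labels do not state this link. Gene coordinates are those of the RefSeq annotation of GRCm38.p6, in which 14522 of the gene numbers were found.

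Counts were tested with edgeR 4.0.16 in R 4.3.3: the quasi-likelihood test with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Skin Ebf2+ and skin Ebf2- were compared in a fit of the 6 skin libraries. Each skin population was compared with bone marrow in a fit of all 10 libraries and 3 groups. A standard error of a log2 fold change (SE) is its size divided by the square root of the quasi-likelihood F. Levels are counts-per-million values (CPM) with TMM scaling over the 10 libraries, as mean ± SD. A fold against a group with 0 reads is given as a lower bound, computed against a floor of 3 counts over that group. The SD and SE hold the spread between libraries. Floors cover counting error only, and amplified reads without molecular identifiers are not independent molecules.

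Before the data were examined, 29 gene lists were fixed, covering lineages, skin layers, other cell types that a sort could hold, stress, signalling and metabolism. The 27 lists other than the sort markers and the sex-linked genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were measured. The test was repeated with an estimated correlation and with fry, which tests whether a list's own genes move one way on balance and does not compare them with other genes. Named genes followed a rule fixed before the data were examined: the sort markers, the 10 largest passing changes each way with at least 10 CPM and no overlap between groups, and up to 2 passing members each way of each list, or the member with the highest level where none passed. Of the rule's list members, some of a list that is only counted are not printed. In the skin comparison the rule left mostly members that did not pass. The genes Myh11, Acta2, Tagln, Notch3, Rgs5, Tinagl1, Epas1, Apod, Trf, Cpz, Cyp2f2, Kcnj8, Ndufa4l2, Apcdd1, Esam, Grem1 and Mfap4 fall outside it there and were chosen after their values were seen.

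The labels number the replicates of each group. Deviations from the group means correlated across genes between the skin libraries of equal number (r = 0.192, 0.235 and 0.624 for numbers 1, 2 and 3). Each was above 0.1 and above every correlation with another number. Unequal pairs of numbers 1 and 2 reached 0.159 and 0.156, also above 0.1. Deviations cancel within a group, so the likeness in number 3 raises the correlations among numbers 1 and 2 together. That likeness could itself come from library preparation, so these values are weak evidence of pairing. The 6 skin libraries come from 3 mice per the design text, and no label says that equal numbers are 1 mouse. The numbers were taken to pair the skin libraries, and in the comparison within skin the fit with the replicate number as a block is printed where it changes a call.

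All pairs of libraries were checked for repeated deposits over genes with at least 10 counts in the pair. Bone marrow 1 and 4 had a Pearson r of 0.992, against 0.758 to 0.853 for the other bone marrow pairs, and a median chi-square of 2.04 times counting noise, against 121 to 228 times. The rule for counting libraries as 1 asked for agreement within counting noise, which the pair did not meet, so both were kept as planned. This does not show that they are separate samples, since 1 sample prepared again would also differ by more than counting noise. Results with the counts of bone marrow 1 and 4 summed as 1 library, an alternative chosen after the data were seen, stand beside the planned ones.

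The procedure was tested on simulated data, with 5 simulations of 200 genes changed by known folds. In the skin comparison edgeR recovered 0.324% of the genes changed 4-fold, 25.4% of those changed 16-fold and 61.0% of those changed 64-fold, with 4.87% false calls; DESeq2 made 42.6% false calls there. In the comparison of skin Ebf2+ with bone marrow the recovered shares were 4.63%, 45.3% and 71.7%, with 3.47% false calls. With a bone marrow library drawn as a copy of another, false calls were 6.89%, and 3.27% after the copies were summed. A raised list of 20 genes was found with an adjusted p of 1.16e-30 at the preset and 0.00599 with an estimated correlation, and 0 of 20 unchanged lists were called. Simulated genes varied independently of each other, so this check could not show false list calls from correlated genes. No pairing of libraries was simulated.

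Alternatives tried were the size factors of DESeq2, upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of at least 10 CPM in at least 3 libraries, a minimum absolute log2 fold change of 1, an adjusted p of 0.01, counts thinned to the smallest library, the block, each library left out, the 2 groups alone, a batch term for the earlier study, and bone marrow 4 or bone marrow 1 to 3 alone. With the batch term each comparison with bone marrow rests on bone marrow 4, the only bone marrow library outside the earlier study. Added after the data were seen were the fits without the skin libraries numbered 3, with bone marrow 1 and 4 summed or both left out, and the block with limma-voom. For the lists, all alternatives but the estimated correlation, fry, the block within skin, the stricter filter and each library left out were also added then.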

Results

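Gene expression was measured in skin cells that express Ebf2, a transcription factor also known from mesenchymal and fat cell precursors, in Ebf2- PαS cells of the same dorsal skin, and in bone marrow mesenchymal stem cells. The libraries held 9.83 to 13.0 M counts in skin Ebf2+ (n = 3), 11.6 to 14.1 M in skin Ebf2- (n = 3) and 18.1 to 39.4 M in bone marrow (n = 4). A floor of 3 counts therefore lay between 0.0761 and 0.305 CPM per library before TMM scaling. Per the design text the skin cells came from 3 mice and the bone marrow cells from 4. Skin came from FVB/N mice of 8 to 12 weeks and bone marrow from C57BL/6 mice of 8 to 10 weeks. Tissue, strain and the markers of the sort thus differ together. Without TMM scaling, Y chromosome genes summed to 46.6 to 96.0 CPM in bone marrow. The sums were 0 to 13.5 CPM in skin Ebf2+ and 0.161 to 32.1 CPM in skin Ebf2-, so the sex of the mice may differ as well. Bone marrow 1, 2 and 3 are labelled as taken from an earlier study, and bone marrow 4 is not.

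The genes used for sorting were measured in each population. Ebf2 (Entrez 13592, chromosome 14, 67233292 to 67430952) stood at 228 ± 82.2 CPM in skin Ebf2+, 63.7 ± 14.6 CPM in skin Ebf2- and 249 ± 100 CPM in bone marrow (SD). Pdgfra, which encodes CD140a, stood at 777 ± 156, 924 ± 170 and 1387 ± 533 CPM in the same order. Ly6a, which encodes Sca1, stood at 1198 ± 179, 1633 ± 428 and 984 ± 322 CPM, and Itgav, which encodes CD51, at 137 ± 67.1, 146 ± 41.02 and 203 ± 36.1 CPM. Ptprc, which encodes CD45, stayed at or below 0.860 CPM in 9 libraries and reached 62.0 CPM in skin Ebf2- 2, where the T cell gene Cd3e stood at 709 CPM. Pecam1, which encodes CD31, was at 20.9 CPM in skin Ebf2+ 3 and at or below 6.36 CPM in the others. Where a population was sorted by a gene, its level there checks the labels and is no finding. The Ptprc and Cd3e levels of skin Ebf2- 2 show leukocyte transcripts in that library.

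The first principal component of the 1000 most variable genes, 41.2% of their variance, separated skin from bone marrow, and the second, 20.4%, separated skin Ebf2+ 1 and 2 from the remaining libraries. Bone marrow 1 and 4 nearly coincided. The skin libraries numbered 3 resembled each other (r = 0.930 across genes, against 0.613 to 0.784 with the other skin libraries). The ribosomal RNA gene Rn45s took 0.593% and 0.170% of their counts, against 3.04% to 12.5% in the other 8 libraries.

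**Figure D1:**
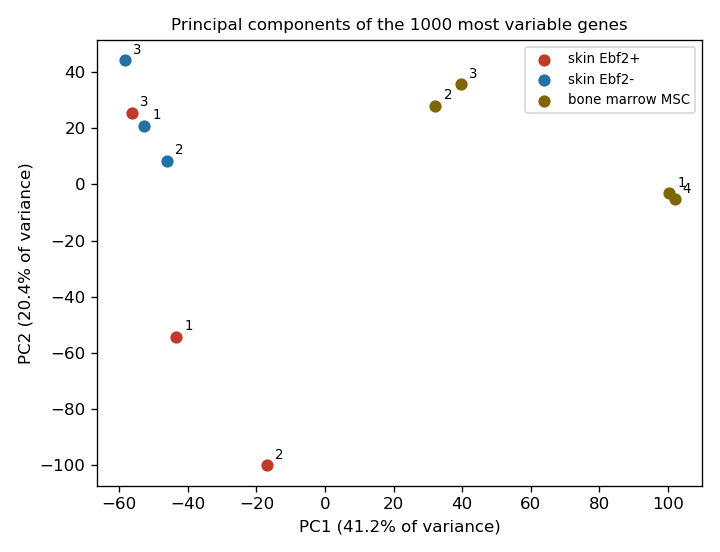
Position of the 10 libraries on the first (horizontal, 41.2% of variance) and second (vertical, 20.4%) principal components of log2 CPM of the 1000 most variable genes; points are libraries, colours are groups and numbers are replicates. The 6 skin libraries lie left of the 4 bone marrow libraries, and bone marrow 1 and 4 nearly coincide.

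The comparison within skin asked how Ebf2+ cells differ from the Ebf2- PαS cells around them. Selection for CD140a and Sca1 is described for the Ebf2- cells alone, so it differs together with Ebf2 status. Genes of smooth muscle and vessel wall cells stood higher in skin Ebf2+. Myh11 (Entrez 17880, chromosome 16, 14194527 to 14292188), the myosin heavy chain of smooth muscle, stood at 379 ± 411 CPM against 0.425 ± 0.388 CPM (SD, n = 3 each). Acta2, smooth muscle actin, stood at 535 ± 405 against 34.2 ± 24.3 CPM, and Notch3, a receptor of vessel wall cells, at 322 ± 379 against 8.53 ± 11.9 CPM. Apod (Entrez 11815, chromosome 16, 31296192 to 31314808), a secreted lipid-binding protein, stood at 4067 ± 1877 against 361 ± 82.7 CPM. Mfap4, a protein of elastic microfibrils, stood lower in skin Ebf2+, at 404 ± 310 against 2331 ± 655 CPM. Grem1, a secreted inhibitor of bone morphogenetic proteins, had 0 reads in skin Ebf2+ and 19.8 ± 7.53 CPM in skin Ebf2-, at least 216-fold lower. In each of these 6 genes the groups did not overlap, which chance gives for 10% of genes at 3 against 3.

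None of these differences passed the test without a block: edgeR's quasi-likelihood test called 0 of 13477 genes. The lowest adjusted p was 0.208, for Tinagl1. An unadjusted p below 0.05 was found for 343 genes, fewer than the share of 0.05 that chance alone gives on average. Ebf2 itself did not pass (edgeR adjusted p = 0.999856, and 0.287 with the replicate number as a block). The count of 0 therefore does not show that the populations are alike. DESeq2 called 116 genes (88 higher and 28 lower in skin Ebf2+) and limma-voom 0, while the authors' deposited table lists 135 (95 higher and 40 lower). With the replicate number as a block, edgeR called 8 genes, and limma-voom called 21 with the same block. Of the 8, Tinagl1 (Entrez 94242, chromosome 4, 130165600 to 130175122), a basement membrane protein, rose by a log2 fold change of 7.69 ± 0.76 (SE; edgeR adjusted p = 0.0364). Myh11 rose by 9.69 ± 0.62 (adjusted p = 0.00533) and Apod by 3.42 ± 0.30 (adjusted p = 0.0247). Epas1, a transcription factor of the response to low oxygen, rose by 5.24 ± 0.43 (adjusted p = 0.0202). Trf, which encodes the iron carrier transferrin, rose by 4.39 ± 0.45 (adjusted p = 0.0364), and an unnamed gene, Entrez 100862094, also rose. Cpz, a carboxypeptidase, fell by 3.41 ± 0.35 and Cyp2f2, a cytochrome P450, by 3.72 ± 0.38 on the log2 scale (edgeR with the block, adjusted p = 0.0364 for each). These 7 named genes moved the same way in 3 of 3 pairs, which adds no support since the block uses these pairs. Their adjusted p over 18 alternatives, the block included, ran from 3.18e-15 to 1 for Myh11, 2.88e-15 to 1 for Tinagl1 and 7.58e-06 to 1 for Apod. It ran from 0.00479 to 1 for Epas1, 0.00227 to 1 for Trf, 0.0177 to 1 for Cpz and 0.00779 to 1 for Cyp2f2. Cpz passed in 3 of the 18 and the other 6 in 4 each. All 7 were chosen after their values were seen, and the groups overlapped for Cpz.

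**Figure D2:**
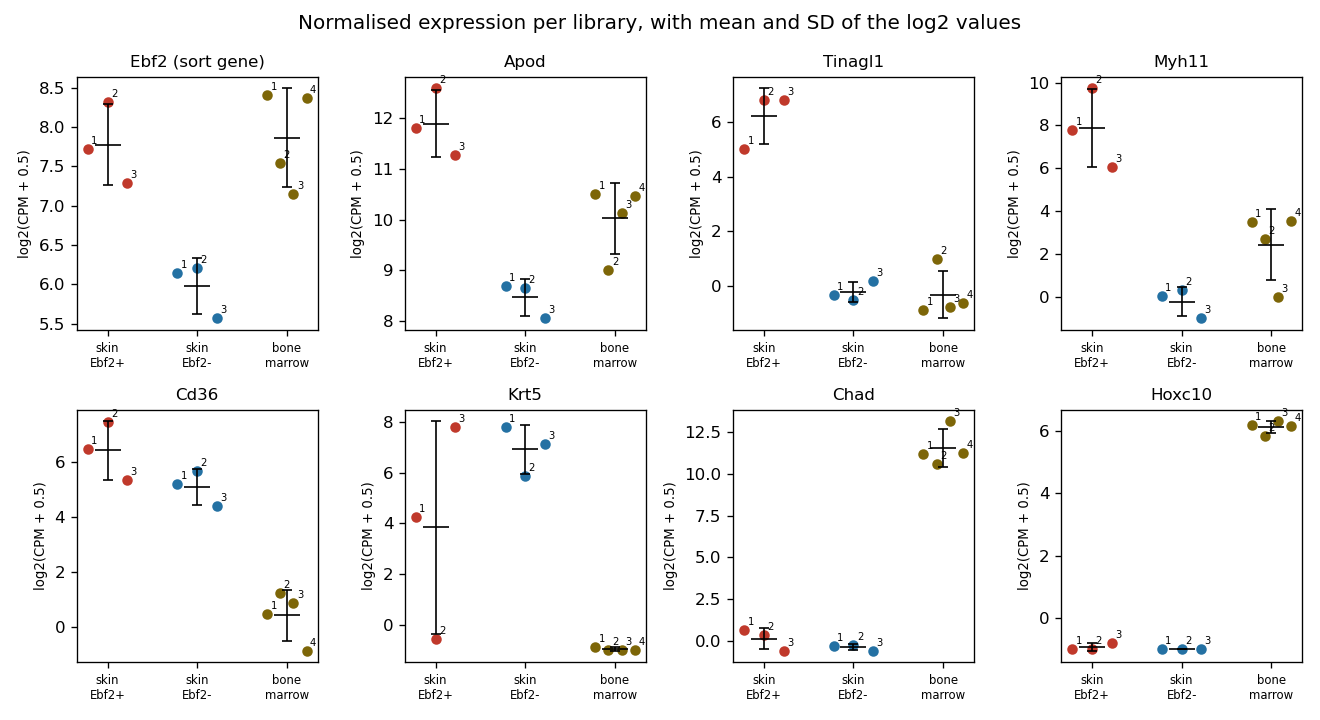
Expression per library of Ebf2, Apod, Tinagl1, Myh11, Cd36, Krt5, Chad and Hoxc10 as log2(CPM + 0.5), with a panel and vertical axis per gene; points are libraries with their replicate numbers, and bars give mean and SD of the log2 values. Apod, Tinagl1 and Myh11 lie higher in the 3 skin Ebf2+ than in the 3 skin Ebf2- libraries, while Chad and Hoxc10 lie highest in the 4 bone marrow libraries.

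The mural cell list (pericytes and smooth muscle of vessel walls) rose in skin Ebf2+. Of its 19 measured members 17 had a positive log2 fold change, 14 were higher when adjusted over the list alone, and 0 passed over all genes without the block (1, Myh11, with it). The median log2 fold change was 3.00, also with the 1 member without reads in skin Ebf2- at its bound, and 1.80 with skin Ebf2+ 2 left out. Camera gave an adjusted p of 3.58e-18 at the preset correlation, and the adjusted p was 0.485 with an estimated correlation. Tagln, a smooth muscle actin-binding protein, stood at 183 ± 167 against 6.27 ± 4.43 CPM, and the pericyte gene Rgs5 at 49.5 ± 73.9 against 0.277 ± 0.479 CPM, of which skin Ebf2+ 2 alone held 135 CPM. Steap4, a metal reductase, stood at 509 ± 167 against 148 ± 45.6 CPM. The pericyte genes Kcnj8 (26.8 ± 12.1 against 73.1 ± 64.9 CPM) and Ndufa4l2 (11.1 ± 12.3 against 36.4 ± 26.3 CPM) had lower means in skin Ebf2+.

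At the preset correlation 7 other lists passed, and no member of them passed over all genes. Chemokines and cytokines rose (camera adjusted p = 0.0353, 14 of 21 members positive), as did endothelial genes (0.0243, 8 of 9 positive). So did the list of immediate early and dissociation stress genes (0.0260, 19 of 23 positive), fixed to cover stress of cell handling. Each of these lists had an adjusted p = 0.485 with an estimated correlation. Cxcl1, a neutrophil attractant, stood at 1240 ± 876 against 264 ± 157 CPM. Of the endothelial members 1 was higher when adjusted over the list alone, the junction gene Esam, at 31.2 ± 22.4 against 0.127 ± 0.165 CPM, and no member of the other 2 lists was. Cell cycle genes fell (camera adjusted p = 7.57e-07; 21 of 26 negative), as did keratinocyte genes (0.00125; 14 of 21), leukocyte genes (0.0137; 9 of 10) and the Wnt pathway (0.0286; 25 of 39). With an estimated correlation the adjusted p was 0.511, 0.71, 0.511 and 0.512 in this order. None of their members passed when adjusted over the list alone. With fry the lowest adjusted p of any list was 0.323. Skin Ebf2- 2 held leukocyte transcripts, with Cd74 at 267 CPM against 5.29 and 12.2 CPM in the others of its group, and the keratin gene Krt5 ranged from 0.175 CPM in skin Ebf2+ 2 to 224 CPM in skin Ebf2+ 3. Apcdd1, a Wnt inhibitor of the papillary dermis, stood at 37.0 ± 17.3 against 227 ± 81.8 CPM. Des, the muscle intermediate filament of the skeletal muscle list, stood at 74.2 ± 84.3 against 5.03 ± 6.23 CPM. With the block the endothelial call was lost (adjusted p = 0.0519), and without the skin libraries numbered 3 the endothelial and Wnt calls were lost (0.574 and 0.294). Without skin Ebf2+ 3 or skin Ebf2+ 1 the 8 lists became 3 or 5, and every list but the mural and cell cycle ones was lost with some library left out (keratinocytes without skin Ebf2+ 2, adjusted p = 0.841). The cell cycle call within skin was lost with the stricter filter (adjusted p = 0.059).

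The comparison of skin Ebf2+ with bone marrow asked how Ebf2-expressing cells of skin differ from mesenchymal stem cells of another tissue. Cartilage and bone genes were lower in skin Ebf2+: Chad (Entrez 12643, chromosome 11, 94565047 to 94569127), a cartilage matrix protein, stood at 0.663 ± 0.458 CPM against 3908 ± 3634 CPM in bone marrow (log2 fold change -12.54 ± 1.16, SE; edgeR adjusted p = 0.000740; n = 3 and 4). Mmp13, the collagenase of cartilage and bone, and Ibsp, bone sialoprotein, had 0 reads in skin Ebf2+, at least 2112-fold and 1146-fold lower. Position genes of the Hox family moved in both directions: Hoxc10 (Entrez 209448, chromosome 15, 102966796 to 102971898) had 1 read in skin Ebf2+ and 69.3 ± 9.003 CPM in bone marrow. Hoxc8 was higher in skin Ebf2+ (65.1 ± 52.5 against 4.75 ± 2.14 CPM; log2 fold change 3.77 ± 0.73, adjusted p = 0.0348). The fatty acid transporter Cd36 was higher in skin Ebf2+ (102 ± 69.2 against 1.03 ± 0.764 CPM, log2 fold change 6.61 ± 0.96, adjusted p = 0.00787). So was Il6, an inflammatory cytokine (213 ± 99.5 against 28.7 ± 6.35 CPM, log2 fold change 2.89 ± 0.47, adjusted p = 0.0134). With bone marrow 1 and 4 summed, Hoxc8 and Il6 did not pass (edgeR adjusted p = 0.113 and 0.0599), while the other genes of this paragraph did.

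In this fit of 10 libraries edgeR called 134 of 14520 genes, 82 higher and 52 lower in skin Ebf2+, with 2124 at an unadjusted p below 0.05. The authors' deposited table lists 1150 genes (653 higher and 497 lower), 131 of the 134 among them. With bone marrow 1 and 4 summed as 1 library the count was 51 (26 higher and 25 lower), and it was 8 with both left out. With a batch term for the earlier study the comparison rests on bone marrow 4, and all 41 passing genes picked by the naming rule kept their sign. Those picked as the largest changes had no overlap between groups by rule. Their sign was thus fixed in advance and adds no support. Within the present study, bone marrow 4 alone gave 1 gene (its single library is assumed to vary like the other groups), and bone marrow 1 to 3 alone gave 51.

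Of 20 chondrocyte genes 5 fell in skin Ebf2+ and 15 did not pass, and 8 were lower when adjusted over the list alone (camera adjusted p = 3.14e-10; adjusted p = 0.108 with an estimated correlation). They included Cytl1, a cartilage cytokine (0.332 ± 0.323 against 325 ± 230 CPM; log2 fold change -9.84 ± 1.08, adjusted p = 0.00146), and Cilp2, a cartilage matrix protein, with 0 reads in skin Ebf2+, at least 3783-fold lower. Outside the list, the cartilage lectin Clec3a had 2 reads in skin Ebf2+ and 566 ± 603 CPM in bone marrow. Of 22 osteoblast genes 5 fell, among them Mmp13 and Ibsp, and over the list alone 9 were lower and 2 higher (camera adjusted p = 6.23e-07; 0.108 as adjusted p with an estimated correlation). Of 24 Hox genes 3 fell and 1 rose, and over the list alone 3 were lower and 2 higher (camera adjusted p = 0.103, not passing; fry adjusted p = 0.000194). With an estimated correlation the adjusted p of the Hox list was 0.222. Hoxa11 had 1 read in skin Ebf2+ and 37.8 ± 12.6 CPM in bone marrow, and Tbx4, a hindlimb transcription factor outside the list, had 0 reads, at least 406-fold lower. Zic1, a transcription factor of dorsal mesoderm, was higher in skin Ebf2+ (17.9 ± 13.9 against 0.0442 ± 0.0411 CPM; log2 fold change 8.45 ± 1.51, adjusted p = 0.0230).

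Keratinocyte genes rose in skin Ebf2+, 8 of 21 over all genes and 19 adjusted over the list alone (camera adjusted p = 3.14e-10; adjusted p = 0.248 with an estimated correlation). Krt5 stood at 18.7, 0.175 and 224 CPM in the 3 skin Ebf2+ libraries against 1 read in bone marrow, and Krt14, with 0 reads in bone marrow, stood at 2.68, 0.349 and 266 CPM. The epithelial adhesion gene Epcam, also with 0 reads in bone marrow, stood at 3.73, 4.19 and 55.7 CPM. The sort as described does not remove keratinocytes by a marker of their own. Bulk RNA cannot tell keratinocytes among the sorted cells from expression of these genes by Ebf2+ cells. Of 21 mural genes 4 rose and 13 were higher over the list alone (camera adjusted p = 3.12e-08; 0.108 as adjusted p with an estimated correlation). They included Myh11 (log2 fold change 5.74 ± 1.15, adjusted p = 0.0390) and Vtn, an adhesive plasma protein (4.58 ± 0.83, adjusted p = 0.0240). Reln, a secreted guidance protein, stood at 99.5 ± 64.5 CPM against 2 reads in bone marrow, and Gcg, the glucagon precursor, at 30.4 ± 24.04 CPM against 0 reads, at least 1026-fold higher. Akr1c18, a steroid-metabolising reductase, was at least 1969-fold higher against 0 reads, at 61.7, 2.10 and 111 CPM in skin Ebf2+ 1 to 3.

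Of 20 adipocyte genes 3 rose in skin Ebf2+, with 6 higher and 2 lower over the list alone (camera adjusted p = 0.0896, not passing; 0.0113 with bone marrow 1 and 4 summed; fry adjusted p = 0.00989). Fabp4, a fatty acid carrier of fat cells, was among them (71.9 ± 57.9 against 1.06 ± 0.643 CPM; log2 fold change 6.08 ± 1.06, adjusted p = 0.0196). Of 24 chemokine and cytokine genes 2 rose, Il6 and the monocyte attractant Ccl2 (3.37 ± 0.65, adjusted p = 0.0341), and over the list alone 8 were higher and 2 lower (camera adjusted p = 0.00719; adjusted p = 0.108 with an estimated correlation). Interferon genes rose (2 of 28, Isg15 and Gbp2; 3 over the list alone; camera adjusted p = 0.00719; 0.441 as adjusted p with an estimated correlation). Antigen presentation and respiratory chain genes rose as lists, with 0 of 23 and 0 of 42 members passing over all genes, 3 and 0 adjusted over the list alone, and 22 and 32 positive (camera adjusted p = 0.000696 and 0.00719; adjusted p = 0.248 and 0.108 with an estimated correlation). Erythroid genes fell as a list, with 0 of 6 members passing over all genes or adjusted over the list alone and all 6 negative (camera adjusted p = 0.0101; adjusted p = 0.377 with an estimated correlation). In the stem cell niche list Lepr, the leptin receptor of marrow stroma, fell (50.3 ± 11.9 against 359 ± 34.3 CPM; -2.83 ± 0.56, adjusted p = 0.0373) and Il6 rose, with 3 higher and 7 lower over the list alone (camera adjusted p = 0.0809, not passing; fry adjusted p = 0.00249). The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, were higher in skin Ebf2+ (3.15 ± 0.45 and 3.35 ± 0.51, adjusted p = 0.00771 and 0.0107). With an estimated correlation the adipocyte and stem cell niche lists stood at adjusted p = 0.222 and 0.219. With fry the keratinocyte, antigen presentation, interferon and erythroid lists did not pass (adjusted p = 0.0888, 0.125, 0.156 and 0.125). The other lists called by camera in this comparison passed with fry. Without the skin libraries numbered 3 the interferon and antigen presentation lists did not pass (camera adjusted p = 0.128 and 0.0712). The erythroid list did not pass without skin Ebf2+ 2 (camera adjusted p = 0.179). With the batch term, which leaves bone marrow 4 as the only library to compare with, the interferon, chemokine and respiratory chain lists did not pass.

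Plac8, a gene of the fascia list, was higher in skin Ebf2+ (log2 fold change 5.69 ± 0.81, adjusted p = 0.00739). The Wnt antagonist Dkk2 (-4.43 ± 0.73, adjusted p = 0.0144), the Wnt co-receptor Lrp5 (-4.11 ± 0.80, 0.0362) and the adhesion gene Ncam1 (-3.90 ± 0.65, 0.0144) were lower. The Y-linked Kdm5d was lower in skin Ebf2+ (edgeR adjusted p = 0.0477), where it had 2 reads against 28.2 ± 15.0 CPM in bone marrow. Its difference may reflect the sex of the mice. Among the largest changes, Lad1, a basement membrane anchor, Cdh6, a cadherin, Olfr558, an olfactory receptor, and Tmem229a had 0 reads in bone marrow. They were at least 1321-fold, 1013-fold, 818-fold and 801-fold higher in skin Ebf2+ (edgeR adjusted p = 0.0408, 0.0341, 0.0217 and 0.0412). In skin Ebf2+ 1 to 3, Lad1 stood at 97.1, 0.087 and 20.2 CPM, Cdh6 at 2.56, 83.7 and 3.83 CPM, Olfr558 at 14.7, 52.4 and 5.63 CPM and Tmem229a at 52.5, 0.087 and 18.6 CPM, so a single library carries most of each mean. The hair keratin Krt25 stood at 318, 0.175 and 3.99 CPM against 2 reads (adjusted p = 0.0485). Slurp1, a secreted Ly6 protein, Cemip, which acts in hyaluronan breakdown, and Eya1, a transcriptional coactivator, had 0 reads in skin Ebf2+ and were at least 817-fold, 317-fold and 128-fold lower (adjusted p = 0.0485, 0.0330 and 0.0212). Of the 41 passing genes that the naming rule picked, all kept their sign with bone marrow 1 and 4 summed and 22 passed. The calls lost were those of Krt14, Epcam, Hoxc8, Il6, Ccl2, Lepr, Zic1, Vtn, Myh11, Isg15, Gbp2, Lrp5, Kdm5d, Lad1, Cdh6, Krt25, Tmem229a, Slurp1 and Eya1. Leaving out bone marrow 1, 2, 3 or 4 gave 44, 75, 57 or 51 genes and leaving out skin Ebf2+ 1 gave 63, against 237 without the skin libraries numbered 3, 1105 with DESeq2 and 223 with limma-voom.

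The comparison of skin Ebf2- with bone marrow set the other skin population against the same bone marrow libraries, so its values share their chance deviations with those above. Cartilage genes were lower in skin Ebf2-: Chad stood at 0.265 ± 0.0977 against 3908 ± 3634 CPM (log2 fold change -13.80 ± 1.21, SE; edgeR adjusted p = 0.000630; n = 3 and 4). Comp, a cartilage matrix protein, stood at 0.395 ± 0.287 against 2439 ± 2013 CPM (-12.57 ± 1.81, adjusted p = 0.00606). Keratins were higher, with Krt5 (Entrez 110308, chromosome 15, 101707069 to 101712905) at 139 ± 81.7 CPM against 1 read. Apcdd1, a Wnt inhibitor, was higher in skin Ebf2- (227 ± 81.8 against 8.51 ± 5.61 CPM; 4.74 ± 0.67, adjusted p = 0.00593), as was Mfap4 (3.57 ± 0.70, adjusted p = 0.0397). Irx2, a homeobox transcription factor, stood at 45.6 ± 20.1 CPM against 1 read.

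EdgeR called 106 of 14520 genes, 57 higher and 49 lower in skin Ebf2-, with 1772 at an unadjusted p below 0.05. The authors' deposited table lists 816 genes (418 higher and 398 lower), 102 of the 106 among them. Upper-quartile scaling shifted the median of all genes by 0.21 (log2) and called 105 genes, 65.7% of them higher against 53.8% with TMM. With bone marrow 1 and 4 summed the count was 47 (20 higher and 27 lower), and it was 13 with both left out. With the batch term the comparison rests on bone marrow 4, and all 35 passing genes picked by the naming rule kept their sign. For those picked as the largest changes, without overlap between groups, the sign was fixed in advance and adds no support. Bone marrow 4 alone gave 2 genes (its single library is assumed to vary like the other groups), and bone marrow 1 to 3 alone gave 46.

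Of 20 chondrocyte genes 5 fell in skin Ebf2- and 11 were lower when adjusted over the list alone (camera adjusted p = 8.12e-16; 0.139 as adjusted p with an estimated correlation). Cytl1 had 1 read, and outside the list Clec3a had 3 reads. Of 22 osteoblast genes 5 fell, with 7 lower and 1 higher over the list alone (camera adjusted p = 3.75e-08; adjusted p = 0.161 with an estimated correlation). They included Dlx5, a transcription factor of bone formation (0.250 ± 0.257 against 55.1 ± 19.98 CPM; log2 fold change -7.75 ± 1.25, adjusted p = 0.0126), and Mmp13, with 2 reads. Stem cell niche genes fell as a list, 1 of 26 over all genes and 3 over the list alone (camera adjusted p = 0.0224; adjusted p = 0.161 with an estimated correlation). Its passing member was Foxc1, a transcription factor of the marrow niche (2.19 ± 2.01 against 67.7 ± 60.7 CPM; -4.95 ± 0.98, adjusted p = 0.0423). Of 24 Hox genes 3 fell and 1 rose, the same counts holding over the list alone (camera adjusted p = 0.0608, not passing; 0.0292 with bone marrow 1 and 4 summed; fry adjusted p = 0.000587). With an estimated correlation the adjusted p of the Hox list was 0.161. Hoxc10, Hoxa11 and Tbx4 had 0 reads in skin Ebf2-, at least 884-fold, 482-fold and 475-fold lower, and so had Mab21l2, at least 738-fold lower. Hoxc8 was higher (log2 fold change 3.67 ± 0.73, adjusted p = 0.0423), and Zic1 was higher too (8.20 ± 1.496, adjusted p = 0.0274). Erythroid genes fell as a list, with 0 of 6 members over all genes and 1 over the list alone (camera adjusted p = 0.0185; 0.424 as adjusted p with an estimated correlation).

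Keratinocyte genes rose in skin Ebf2-, 8 of 21 over all genes and 18 adjusted over the list alone (camera adjusted p = 1.43e-17; adjusted p = 0.161 with an estimated correlation). Krt15 stood at 69.0 ± 54.5 CPM and Krt1 at 37.8 ± 26.4 CPM against 1 read each in bone marrow. Here too, keratinocytes among the sorted cells cannot be told apart from expression by skin Ebf2- cells. Antigen presentation genes rose (2 of 23 over all genes, 6 over the list alone, all 23 positive; camera adjusted p = 4.54e-06; 0.161 as adjusted p with an estimated correlation). Psmb8, a subunit of the immunoproteasome, rose by 2.76 ± 0.56 (adjusted p = 0.0437). Leukocyte genes rose (1 of 12, 5 over the list alone; camera adjusted p = 0.00235; adjusted p = 0.367 with an estimated correlation). The passing member was Cd74, the invariant chain of MHC class II (log2 fold change 8.76 ± 1.68, adjusted p = 0.0355), which stood at 267 CPM in skin Ebf2- 2 against 5.29 and 12.2 CPM in the others. Cell cycle genes rose as a list with 0 of 26 members passing over all genes or adjusted over the list alone and 21 positive (camera adjusted p = 0.000262; adjusted p = 0.433 with an estimated correlation). Interferon genes rose (1 of 28, Gbp2, and 3 over the list alone; camera adjusted p = 0.0185; 0.513 as adjusted p with an estimated correlation). Papillary dermis genes rose as well (1 of 18, Apcdd1, and 5 over the list alone; camera adjusted p = 0.0346; adjusted p = 0.401 with an estimated correlation). Without the skin libraries numbered 3 the interferon and papillary dermis lists did not pass in this comparison (camera adjusted p = 0.322 and 0.244). The batch term ended both calls (0.388 and 0.156) and that of the stem cell niche (0.142), and the erythroid call was lost without skin Ebf2- 3 (0.0774). The cell cycle call was lost with the stricter filter (0.14). With fry the leukocyte, erythroid, interferon, papillary dermis and cell cycle lists did not pass (adjusted p = 0.0716, 0.258, 0.199, 0.0609 and 0.203). The other lists called by camera in this comparison passed with fry.

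Further genes were higher in skin Ebf2-: Cd36 (log2 fold change 5.12 ± 0.90, adjusted p = 0.0233), Plac8 (5.49 ± 0.80, 0.00653) and the potassium channel gene Kcnj8 (4.63 ± 0.85, 0.0278). So were Hspa1a and Hspa1b (3.86 ± 0.47 and 4.03 ± 0.52, edgeR adjusted p = 0.00259 and 0.00370), whose reads cannot be assigned between the copies with certainty. Akr1c18 was at least 1284-fold higher against 0 reads, and Sectm1a and Fgfr4, a fibroblast growth factor receptor, stood at 187 ± 170 and 45.6 ± 45.1 CPM against 2 reads each. The desmosome gene Dsg1a and Ly6d, a gene of epidermal cells, had 0 reads in bone marrow and were at least 1057-fold and 625-fold higher (adjusted p = 0.0428 each), and the desmosome gene Dsc3 stood at 33.9 ± 27.8 CPM against 1 read (0.0281). Cemip, with 0 reads in skin Ebf2-, was at least 370.0-fold lower (adjusted p = 0.0319). Of the 35 passing genes that the naming rule picked, all kept their sign with bone marrow 1 and 4 summed and 21 passed. The calls lost included those of Krt15, Krt1, Fgfr4, Hoxc8, Zic1, Mfap4, Kcnj8, Cd74, Psmb8, Gbp2, Dsg1a, Ly6d and Dsc3. Leaving out bone marrow 1, 2, 3 or 4 gave 43, 57, 58 or 46 genes and leaving out skin Ebf2- 1, 2 or 3 gave 38, 34 or 55, against 794 with DESeq2, 293 with limma-voom and 262 in a fit of these 2 groups alone.

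The closeness of each skin population to bone marrow was compared over all genes that passed the filter. The mean Pearson r of a library with the 4 bone marrow libraries was 0.682 ± 0.020 in skin Ebf2+ and 0.712 ± 0.038 in skin Ebf2- (SD, n = 3 each). The difference was -0.030 (two-sided exact permutation test over 20 splits, p = 0.3). The smallest p this test can give is 0.1, so it could not have passed. Skin Ebf2+ lay below skin Ebf2- in each of the 3 numbers, at 0.704 and 0.739, 0.676 and 0.728, and 0.665 and 0.668, and this pairing was not tested.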

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

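Values were checked in bone marrow, the only group of 4, for a library whose gap to its nearest neighbour took an unusually large share of the group's range. Of 68 genes and library measures 13 passed the limit. Chance passes about 5% where the 4 libraries are independent, which is doubtful here since bone marrow 1 and 4 are nearly alike, and 8 of the 13 passed by construction, as below. The genes checked were those the text names.

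Bone marrow 3 lay far above the others for 3 cartilage genes: Cilp2 at 180, 150, 875 and 183 CPM in bone marrow 1 to 4 (gap share 0.954), Clec3a at 247, 317, 1469 and 233 CPM (0.933), and Chad at 2314, 1559.5, 9327 and 2429.5 CPM (0.888). Bone marrow 2 lay below the others for Mab21l2, at 11.8 CPM against 70.0, 76.1 and 73.7 CPM (gap share 0.904), and above them for Ptprc, at 0.391 CPM against 0, 0.0300 and 0.05001 CPM (0.872).

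In 8 genes a single library alone held 1 or 2 reads, which gives a gap share of 1 by construction. These were Krt5 (bone marrow 1, 0.0490 CPM, 1 read), Reln (bone marrow 2, 0.0978 CPM, 2 reads), and Krt15, Krt1, Irx2 and Dsc3 (bone marrow 4, 0.05001 CPM, 1 read each), with Sectm1a and Krt25 (bone marrow 4, 0.10003 CPM, 2 reads each).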

How the results depend on the processing

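The alternatives without the skin libraries numbered 3, with bone marrow 1 and 4 summed or both left out, and the block with limma-voom were chosen after the data were seen. The choice to keep bone marrow 1 and 4 separate follows the plan, and was settled after both fits had been run. Except where a sentence names it, the cause of a change was not tested.

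Within skin the count of genes was 0 in 16 of 20 alternatives. It was 116 with DESeq2, which made 42.6% false calls in the simulation of this comparison. That simulation held no pairs, so its share of false calls need not hold for these libraries. With the replicate number as a block, which pairs the skin libraries, the count was 8, with 9 on thinned counts and 21 with limma-voom. Leaving out 1 library at a time gave 0 throughout. The count of lists, 8, was 0 with an estimated correlation, 0 with fry and 5 with the stricter filter, and ran from 3 to 9 with 1 library left out. In the other alternatives it was 6 to 9. The block changed no list call within skin but the endothelial one.

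Between skin Ebf2+ and bone marrow the count of 134 became 22 at an adjusted p below 0.01, 1105 with DESeq2, 223 with limma-voom and 76 with the 2 groups alone. It was 7 with the batch term, 1 with bone marrow 4 alone, 51 with bone marrow 1 to 3 alone, 51 with bone marrow 1 and 4 summed, 8 with both left out and 237 without the skin libraries numbered 3. With 1 library left out it ran from 44 to 200. Among the 134, more genes were higher than lower in skin Ebf2+. The reverse held, among other fits, with the block (29 higher and 38 lower) and with the 2 groups alone (36 and 40). It also held without the skin libraries numbered 3 (108 and 129). The count of lists, 9, was 0 with an estimated correlation, 6 with the batch term and with bone marrow 4 alone, and 8 to 12 otherwise.

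Between skin Ebf2- and bone marrow the count of 106 became 35 at an adjusted p below 0.01, 794 with DESeq2, 293 with limma-voom and 262 with the 2 groups alone. It was 9 with the batch term, 2 with bone marrow 4 alone, 46 with bone marrow 1 to 3 alone, 47 with bone marrow 1 and 4 summed and 13 with both left out. With 1 library left out it ran from 34 to 58. The count of lists, 10, was 0 with an estimated correlation, 7 with the batch term and with bone marrow 4 alone, and 7 to 13 otherwise.

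Skin and bone marrow libraries share only a number: deviations of equal numbers correlated at 0.0842, -0.0444 and 0.124 for skin Ebf2+ and 0.0345, -0.0365 and 0.0808 for skin Ebf2-. With the number as a block all the same, 67 and 69 genes were called, and 19 of 41 and 24 of 35 rule-picked genes passed. The niche list and the list of immediate early and dissociation stress genes (camera adjusted p = 0.0478 and 0.0475) passed for skin Ebf2+. The respiratory chain (0.0270) passed for skin Ebf2-. With an estimated correlation none of these lists passed (adjusted p = 0.267, 0.503 and 0.276). Ebf2 in skin Ebf2+ against bone marrow turned to 0.0662 and Pecam1 to -1.93.

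The changes of sign concerned sort genes and Cd74, none of them called in the fits concerned (adjusted p 0.159 to 1). Within skin, Itgav (-0.09) was 0.0115 without the skin libraries numbered 3 and ran from -0.51 to 0.23 with 1 library left out, and Cd74 (-1.52) ran from -2.75 to 1.93. Between skin Ebf2+ and bone marrow, Ebf2 (-0.13) was 0.0389 with bone marrow 1 to 3 alone, 0.00915 with bone marrow 1 and 4 summed, 0.48 with both left out and 0.0840 without the skin libraries numbered 3, and ran from -0.48 to 0.0831 with 1 library left out. Ly6a (0.28) was -0.00523 with the batch term and -0.00713 with bone marrow 4 alone. Pecam1 (0.69) was -3.23 with limma-voom and -9.26 without the skin libraries numbered 3, and ran from -9.22 to 1.19 with 1 library left out. Ptprc (1.29) was -4.12 without the skin libraries numbered 3 and ran from -4.08 to 3.14.

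Upper-quartile scaling shifted the median of all genes by -0.12 within skin and by 0.11 and 0.21 for skin Ebf2+ and skin Ebf2- against bone marrow. The difference in similarity to bone marrow stayed between -0.0479 and -0.00458 in 12 alternatives, with too few libraries for its test to pass. Depth limits genes below about 0.305 CPM in the smallest library, where 3 counts is the level. Bone marrow 4 alone, a single library, was assumed to vary like the other groups. With the batch term the comparisons also rest on bone marrow 4, so calls lost there do not show an effect of the study.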

Other observations

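Genes of the X and Y chromosomes differed between libraries within groups. Xist, which silences an X chromosome in female cells, stood at 3095, 3375 and 132 CPM in skin Ebf2+ 1 to 3, at 2182, 2183 and 48.8 CPM in skin Ebf2- 1 to 3, and at 2210, 1677, 0.389 and 2001 CPM in bone marrow 1 to 4. Without TMM scaling, Y chromosome genes summed to 0.102, 0 and 13.5 CPM, to 0.161, 6.22 and 32.1 CPM, and to 53.5, 46.6, 96.0 and 47.3 CPM in the same order. In number 2, Y genes were read in skin Ebf2- (6.22 CPM) but not in skin Ebf2+ (0), so these levels leave open whether equal numbers are 1 mouse. The dividing cell gene Mki67 stood at 162, 96.4 and 4.54 CPM in skin Ebf2- 1 to 3, against 7.33, 11.1 and 8.05 CPM in skin Ebf2+, and the stress-induced Fos at 1495, 1467 and 5327 CPM against 2005, 1891 and 6501 CPM.

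Several lists passed in none of the 3 fits that the report leads with. Their lowest camera adjusted p in those fits was 0.0896 for the adipocyte lineage, 0.91 for brown and beige fat, 0.694 for extracellular matrix, 0.224 for reticular dermis and fascia and 0.675 for dermal papilla and sheath. It was 0.294 for Schwann cells, 0.121 for melanocytes, 0.1 for skeletal muscle, 0.17 for complement, 0.0608 for Hox genes and 0.571 for glycolysis. With bone marrow 1 and 4 summed, the adipocyte lineage passed for skin Ebf2+ (0.0113) and skin Ebf2- (0.0350), as did Hox genes (0.0292) and the respiratory chain (0.0292, against 0.0608 unsummed) for skin Ebf2-. Other alternatives also passed some of them, among them the stricter filter for the adipocyte lineage (0.00158) and Hox genes (0.00258), thinned counts for skeletal muscle (0.00558), and a left-out library for complement (0.0059), melanocytes (0.00616) and reticular dermis (0.0326). With fry the adipocyte lineage and Hox genes passed for both, at 0.00989 and 0.000194 for skin Ebf2+ and at 0.0207 and 0.000587 for skin Ebf2-.

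All the tests below, of the 3 patterns and of the regroupings, were chosen only after the result was seen.

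Bone marrow 1 and 4 were nearly alike. Their median chi-square was 2.04 times counting noise, and the lowest other bone marrow pair stood 59.0 times higher. The value of 59.0 restates the likeness that raised the question, so it excludes nothing. A single RNA or cDNA sample sequenced 2 times could give the value of 2.04, and of the pair the labels put bone marrow 1, but not 4, in the earlier study. No biological explanation was tested; sequencing records of both libraries would decide.

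The skin libraries numbered 3 lay apart from the other skin libraries. A difference in preparation or RNA quality could account for this, with Rn45s at no more than 0.593% of their counts against at least 3.04% in the other 8. The deviations of these libraries correlated at 0.624 with and 0.623 without genes on X and Y, so those genes alone do not carry the likeness. Leaving them out hardly moved the value, and this cannot exclude sex acting through other genes. Xist stood at 132 and 48.8 CPM in these libraries against 2182 to 3375 CPM in the other skin libraries. The Ebf2 ratio of 3.32 in number 3, against 2.98 and 4.32 in the others, argues against full mixing of the sorted populations. A single gene with so few ratios to compare cannot exclude partial mixing. Sex acting through other genes was not tested, nor was any other biological explanation.

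Mural cell genes were higher in skin Ebf2+ in each number, with medians of 1.98, 4.74 and 2.25 in numbers 1, 2 and 3 on the log2 scale and 13 of 19 members higher in all 3. Without skin Ebf2+ 2 the median of the list fell from 3.00 to 1.80 and stayed above 0, which excludes that library as the whole cause. Mural or other smooth muscle cells inside the Ebf2+ gate could give the lowest median of 1.98. Expression of these genes by all Ebf2+ cells could as well, and bulk RNA cannot separate these. Single-cell RNA sequencing or staining of the sorted cells for Myh11 and Ebf2 would tell expression by some cells from expression by all. Selection for CD140a and Sca1, described for the Ebf2- cells alone, cannot be told apart here from Ebf2 status.

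Regrouping the libraries gave the following. Within skin the splits were too few: 10 of 10 reached the real count of 0 genes (highest other 0), 1 of 4 reached the 8 genes of the block (highest other 0), and 1 of 10 reached the 8 lists (highest other 5). For skin Ebf2+ and bone marrow 1 of 35 splits reached 134 genes (highest other 0) and 6 of 35 reached 9 lists (highest other 10). For skin Ebf2- and bone marrow 1 of 35 reached 106 genes (highest other 0) and 5 of 35 reached 10 lists (highest other 12), so other groupings gave as many lists. Since bone marrow 1 and 4 are nearly alike, the 35 splits are fewer in effect. With these summed, 10 splits were too few, with 51 and 47 genes and 1 of 10 reaching each (highest other 0).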
